A study of Mus musculus with 6 samples.

How the data were processed

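The data were 6 dual-channel arrays of mouse RAW 264.7 cells, untreated or treated for 1 h with LPS (100 ng/ml) and LBP (100 pM). The series title and part of the descriptions name the line RAW 264.4, and it was taken for RAW 264.7, as the sample titles have it. Per the labels, 3 arrays carried treated RNA in Cy5 and 3 carried it in Cy3, each numbered as sets 1 to 3. The deposited values are log2 ratios of the 2 channels, 1 for each of 16281 probes on each array. The base was read from the values, since between 99.7284% and 99.8880% of the non-zero values on each array are log10 numbers of 6 digits divided by log10 of 2 (relative tolerance 1e-13), while 0% are under base 10 or the natural base. The scanner, background correction and normalization used by the authors were not given in the sources used here. The array medians of the measured ratios were 0.0054, 0.0159 and 0.0043 with treated RNA in Cy5 and 0.0078, 0.0069 and 0.0047 with treated RNA in Cy3, for sets 1, 2 and 3, so the arrays were centred near 0, and how they were centred remained unknown. No intensities were used here, so signal over background was unknown and the number of arrays alone is given as the limit of precision.

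The direction of the ratios was not stated. The labels call the Cy5 sample the test and the Cy3 sample the control on all 6 arrays, so the ratio was likely Cy5 over Cy3. Among the 200 probes of largest mean absolute value, 123 had opposite signs in the 2 orientations, 114 of them higher and 9 lower in treated RNA under that reading, and 77 had the same sign. The values were therefore taken as not yet turned, and the arrays with treated RNA in Cy3 were multiplied by -1. The opposite signs do not tell Cy5 over Cy3 from Cy3 over Cy5, so the direction was taken from these labels. Of the genes fixed by name beforehand, Tnf (2.44), Il1b (2.54), Ccl4 (2.40), Tnfaip3 (1.70), Egr1 (5.13), Ier3 (1.78) and Ptgs2 (1.16) were then higher in treated RNA. Il6, Cd14, Actb and Gapdh were not called, and Tlr4 was lower (-0.57). With Cy3 as the numerator, LPS would have lowered Tnf, Il1b and the others that rose, which argues against that reading.

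An exact 0 was treated as no measured ratio. Zeros made up 8.99%, 17.7% and 10.8% of the values with treated RNA in Cy5 and 11.8%, 23.9% and 12.1% with treated RNA in Cy3. Of the probes, 11442 (70.28%) had a ratio on all 6 arrays, 4839 had a 0 on at least 1 array, and 956 of these had a 0 on all 6. The annotation gave 1 gene symbol for 13738 probes, several for 52 and none for 2491. Gene identifiers of 13694 probes were found in a RefSeq table of the mouse assembly GRCm38.p6, which was used only to update names and changed 0 symbols. No genome build is named for the probes, so no coordinates are given. Probes with 1 symbol and a ratio on all arrays (9968) were averaged by symbol to 8331 genes, of which 1493 had several probes.

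In each set the turned arrays of both orientations were averaged to 1 replicate, so that a common dye effect cancels, and the 3 averages were tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided, 2 residual degrees of freedom and a prior of 4.08 for genes). Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say whether the sets are separate cultures, so the p-values measure only the spread between these samples, which may be technical. Dye effects were tested in the same way on the unturned averages. The 19 gene lists were tested against all other genes with camera (limma, preset correlation 0.01) and adjusted over the 19 lists. Camera with an estimated correlation, fry and Fisher's exact test were alternatives. The lists were immediate early transcription factors, cytokines and growth factors, chemokines, the NF-kappaB pathway and its feedback, MAP kinase feedback and mRNA decay, TLR4 receptor and signalling components, interferon-stimulated genes, inflammatory enzymes and effectors, surface receptors and costimulation, macrophage identity, cell cycle, apoptosis regulators, cholesterol synthesis and transport, heat shock and unfolded protein response, ribosomal proteins, housekeeping reference genes, lymphocyte markers, fibroblast and epithelial markers, and osteoclast markers.

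The design, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the 12 genes of largest positive and the 8 of largest negative mean ratio among genes past the test with the same sign on all 6 arrays, 16 genes fixed by name (Tnf, Il1b, Il6, Cxcl2, Ccl3, Ccl4, Nfkbia, Tnfaip3, Egr1, Junb, Ier3, Ptgs2, Tlr4, Cd14, Actb and Gapdh) and up to 4 measured members of each list with the largest absolute ratio. It gave 91 genes in the fit, and genes outside it are marked as named after their values were seen. Of these 91, 25 had several probes with a ratio on all 6 arrays. The signs of those probes differed for Gapdh and Ifit3, and their calls differed for Tlr4, Ifit3 and Cdc25b. Incomplete probes, some of which disagreed with the complete probe of their gene, are not in this count. They were used only in the alternatives that drop the filter on missing ratios or keep zeros as ratios.

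The alternatives chosen then left out each set in turn, used only 1 dye orientation, treated the 6 arrays as separate samples with a dye term, fitted the set number as a random block, used robust eBayes, set array medians to 0, applied quantile normalization to the turned arrays, dropped the filter on missing ratios, kept only probes at or above the median of all probes in mean absolute log2 ratio, took the median of the probes of a gene, left out probes with a dye effect, or used an adjusted p under 0.01. Keeping zeros as ratios, and the dye fit to 6 separate arrays, were alternatives chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and R 4.3.3 with statmod 1.5.0 were used.

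The fit was tested on simulated data with the spread of these arrays and 8331 genes, of which 50 were changed at each size. The noise was drawn independently for each gene and array, with the same SD for a gene on all arrays. Correlation between genes or between arrays, and arrays of unequal noise, were therefore not simulated. The shares of false calls on the real arrays may differ from those here. The treatment test recovered 12 of 50 at a log2 change of 0.25, 39 at 0.5, 47 at 1 and 49 at 2, with 3 false calls among 150. The dye test recovered 16, 36, 47 and 49 of 50 at the same sizes, with 10 false calls among 158. Camera and fry called a simulated list of 17 genes raised by 0.25 (adjusted p = 1.27e-22 and adjusted p = 0.0408), camera with an estimated correlation did not (adjusted p = 0.158), and each called 0 of the 18 other lists.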

Results

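RNA was compared between untreated RAW 264.7 cells, a mouse macrophage line, and the same line treated for 1 h with lipopolysaccharide (LPS, 100 ng/ml), an outer membrane component of Gram-negative bacteria, plus LPS-binding protein (LBP, 100 pM), a serum protein that carries LPS to its receptor. Total RNA of both kinds was hybridised together on each of 6 dual-channel arrays, 3 with treated RNA in Cy5 and 3 with treated RNA in Cy3. The labels number the arrays of each orientation as sets 1 to 3, and the arrays that share a number were averaged, so n = 3 sets throughout. With orientation means removed, arrays that share a number correlated at r = -0.0077, -0.281 and -0.0943, so the numbers did not pair them. The SD over set averages can therefore be smaller than the spread between single arrays. The p-values rest on the same set averages, so they share this limit and can be too small. Of 16281 probes, 11442 had a ratio on all 6 arrays, and their probes with a gene symbol gave 8331 genes. Values are mean log2 ratios of treated over untreated RNA ± SD over the 3 sets, so that 1 stands for a doubling. Their sign rests on Cy5 being the numerator of the deposited ratios, which follows from the labels naming the Cy5 sample the test and the Cy3 sample the control, and every sign would turn if the numerator were Cy3. The rises of Tnf, Il1b and other genes fixed by name beforehand argue against a Cy3 numerator. The number of arrays limits the precision.

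The comparison asked which transcripts differ within 1 h of LPS and LBP. Among genes with a ratio on all 6 arrays, Egr1, an immediate early transcription factor, rose most, by 5.13 ± 0.16 (limma, adjusted p = 1.18e-06). Its relative Egr2 rose by 3.79 ± 0.25, and Nfkbiz, an atypical inhibitor protein of the NF-kappaB family, rose by 3.72 ± 0.17. Cd83, a surface marker of activated antigen-presenting cells, rose by 3.56 ± 0.08, or 11.8-fold. Among secreted factors, Ifnb1, which encodes interferon beta, rose by 3.00 ± 0.44, the chemokine gene Cxcl10 by 3.00 ± 0.24 and Csf3, the granulocyte colony-stimulating factor, by 2.66 ± 0.24. With incomplete probes included, Csf3 averaged 1.83 and did not pass (adjusted p = 0.0585), as its other probe, measured on 3 arrays, averaged -0.83, and with zeros kept as ratios Csf3 passed at 1.12. The 12 named genes with the largest rises also held Phlda1 at 3.37 ± 0.19, the growth inhibitor Btg2 at 3.04 ± 0.20, the growth regulator Myc at 2.79 ± 0.18 and Traf1, a signalling adaptor, at 2.72 ± 0.23. Lynx1, a membrane-anchored modulator of acetylcholine receptors, rose by 2.97 ± 0.05 on its complete probe, whereas its other probe gave 0.24 and -0.27 on the 2 arrays where it was measured, and Lynx1 averaged 1.48 with zeros kept as ratios.

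Falls were smaller than rises. Sfi1, a centrosome protein gene, fell by 1.54 ± 0.08, or 2.91-fold (adjusted p = 1.46e-05), and Id2, an inhibitor of helix-loop-helix transcription factors, fell by 1.39 ± 0.10. Gpr146, an orphan-type receptor gene, fell by 1.35 ± 0.05 and Slx1b, a nuclease subunit gene, fell by 1.22 ± 0.14. Inka1 fell by 1.12 ± 0.04, the noncoding RNA gene Pvt1 fell by 1.07 ± 0.08, the Polycomb gene Cbx8 fell by 1.03 ± 0.12 and the adaptor gene Dok1 fell by 0.98 ± 0.15. In all, 1097 genes changed, 580 upward and 517 downward, which was 13.2% of the genes tested. Of these, 81 rose and 7 fell by 2-fold or more, and 22 rose and 0 fell by 4-fold or more. The median of the rises was 0.34 and that of the falls was -0.28. The sign was the same on all 6 arrays for 949 of the 1097. Calls made from the same arrays favour this, and among all 8331 genes tested 1592 had one sign on all 6. Without set 1, 499 genes passed the test, 490 of them among the 1097, against 831 without set 2 and 832 without set 3. The arrays with treated RNA in Cy3 alone gave 649. A fit without a set has fewer averages and residual degrees of freedom. Calls can therefore be lost there though the ratio hardly moves, which alone is no sign that a gene depends on that set. This loss is the same whichever set is left out, so it does not account for the lower count without set 1. With probes that lacked some ratios included, 655 genes passed.

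**Figure D1:**
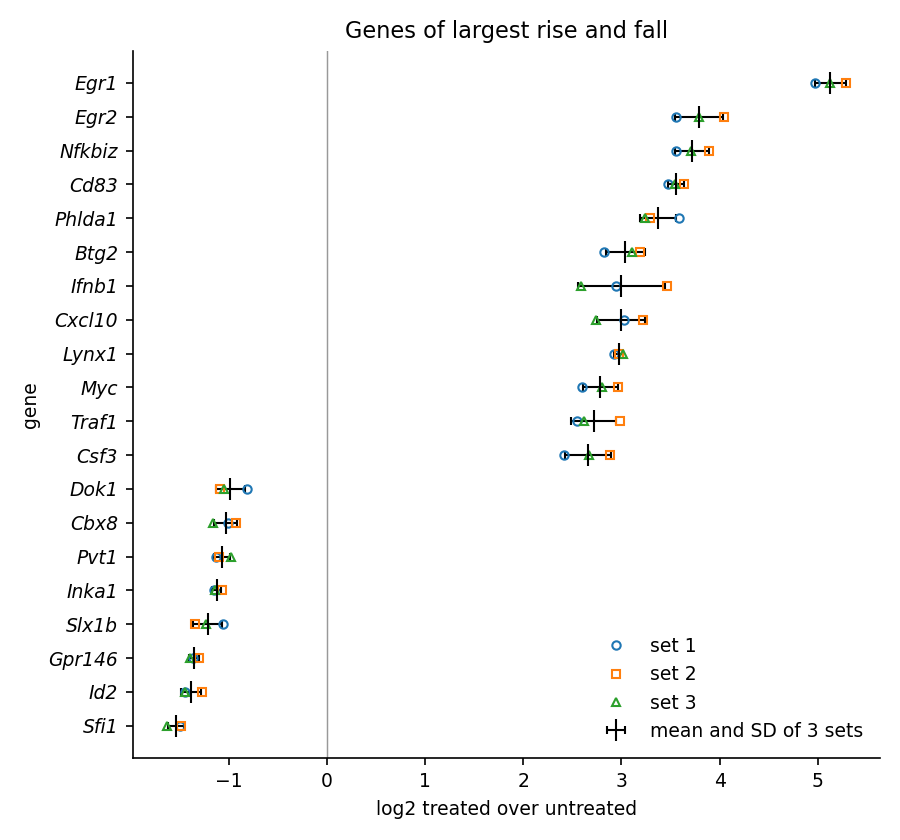
Log2 ratio of treated over untreated RNA (horizontal axis) for the 12 genes with the largest rises and the 8 with the largest falls among genes past the test and of one sign on all 6 arrays, with the mean and SD over the 3 sets and each set as a point. The rises run from 2.66 for Csf3 to 5.13 for Egr1, and the falls reach -1.54 for Sfi1.

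Among the immediate early transcription factors, 21 of 29 measured genes rose and 4 fell, with the same counts adjusted over the list alone (21 and 4), and the list shifted upward (camera, mean 0.99, adjusted p = 5.69e-14). The adjusted p was 0.113 with an estimated correlation. Egr1, Egr2, Btg2 and Myc were the members that rose most, and Ier3, a stress response gene, rose by 1.78 ± 0.19. The 4 that fell, named after their values were seen, were the transcription factor genes Fos, which fell by 0.25 ± 0.04, Nr4a2, which fell by 0.38 ± 0.13, Klf2, which fell by 0.47 ± 0.23, and Klf4, which fell by 0.28 ± 0.09. Without set 1, Fos (-0.27), Nr4a2 (-0.35) and Klf2 (-0.40) no longer passed the test, and without set 3 Klf4 (-0.27) did not. With treated RNA in Cy3 alone, none of the 4 passed (Fos -0.20, Nr4a2 -0.23, Klf2 -0.28 and Klf4 -0.25). With incomplete probes included, Klf2 (adjusted p = 0.071) and Klf4 (adjusted p = 0.0568) did not pass, and Nr4a2 averaged -0.04 (adjusted p = 0.708), as its other probe averaged 0.42 over 5 arrays. The value of Fos is the mean of probes at -0.45 and -0.04, of which the first passed. Junb, one of the genes fixed for naming, was listed at 0 on all arrays.

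Of the 17 measured genes of the NF-kappaB pathway and its feedback, 15 rose and 0 fell, and the same numbers held adjusted over the list alone, with a mean of 1.09 (camera, adjusted p = 2.23e-18). With an estimated correlation the adjusted p was 0.113. Besides Nfkbiz and Traf1, Birc3, an inhibitor of cell death, rose by 1.71 ± 0.07 and Tnfaip3, which encodes the ubiquitin-editing enzyme that restrains NF-kappaB, rose by 1.70 ± 0.28. The remaining 2, named after their values were seen, were Tnip2 at -0.06 ± 0.08 and Traf2 at 0.10 ± 0.06. Nfkbia, the classical inhibitor gene of the pathway, lacked ratios on some arrays and averaged 1.58 over 2 sets (limma, adjusted p = 0.00366) when incomplete probes were included.

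For MAP kinase feedback and mRNA decay, 16 of 26 genes rose and 2 fell, also adjusted over the list alone (16 and 2), with a mean of 0.82 (camera, adjusted p = 2.79e-11, and adjusted p = 0.113 with an estimated correlation). The phosphatase gene Dusp2 rose by 2.62 ± 0.10, the kinase gene Pim1 by 2.43 ± 0.10 and Zfp36, whose protein destabilises cytokine mRNAs, by 2.14 ± 0.13. Rgs2, a regulator of G-protein signalling, fell by 0.79 ± 0.14, and the phosphatase gene Dusp14 fell by 0.24 ± 0.07, both named after their values were seen. With set 1, 2 or 3 left out, Dusp14 did not pass the test, at -0.28, -0.24 and -0.20.

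Among cytokines and growth factors, 11 of 21 genes rose and 0 fell (14 and 0 adjusted over the list alone), with a mean of 0.93 (camera, adjusted p = 1.02e-12). The adjusted p was 0.113 with an estimated correlation. Tnf, the tumour necrosis factor gene, rose by 2.44 ± 0.19, or 5.42-fold, and Il1b, which encodes interleukin 1 beta, rose by 2.54 ± 0.16. Il6, another inflammatory cytokine gene, averaged 0.07 ± 0.08 (adjusted p = 0.382), and its mean was -0.02 on the arrays with treated RNA in Cy5. Il12a, a cytokine subunit gene named after its values were seen, rose by 0.35 ± 0.10 (adjusted p = 0.00724) but averaged -0.46 on the arrays with treated RNA in Cy5 (adjusted p = 0.0429).

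The chemokines had 6 of 16 genes that rose and 0 that fell (7 and 0 adjusted over the list alone), with a mean of 0.55 (camera, adjusted p = 0.000166, and adjusted p = 0.136 with an estimated correlation). Behind Cxcl10, Ccl4 rose by 2.40 ± 0.13, Ccl2, a monocyte attractant, by 1.09 ± 0.24 and Ccl5, a T cell attractant, by 0.86 ± 0.13. With incomplete probes included, Cxcl2, a neutrophil attractant, averaged 4.96 over 3 sets (limma, adjusted p = 0.00942) and Ccl3 averaged 1.37 over 2 sets (adjusted p = 0.0261), while Ccl5 averaged 0.57 and did not pass (adjusted p = 0.0675). The other probe of Ccl5 averaged 0.17 over 5 arrays, with zeros kept as ratios Ccl5 passed at 0.50, and that of Cxcl2 was listed at 0 on all arrays.

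Inflammatory enzymes and effectors followed with 16 of 29 genes that rose and 0 that fell, counts that were equal adjusted over the list alone, and a mean of 0.47 (camera, adjusted p = 5.44e-09). That adjusted p was 0.113 with an estimated correlation. Clec4e, a receptor for microbial glycolipids, rose by 1.96 ± 0.15, Marcksl1, a regulator of the actin skeleton, by 1.69 ± 0.17 and F3, the tissue factor gene, by 1.58 ± 0.30. The acute phase gene Saa3 rose by 1.54 ± 0.25, and Ptgs2, the inducible cyclooxygenase gene of prostaglandin synthesis, rose by 1.16 ± 0.29 (adjusted p = 0.00126). Acod1, the itaconate synthesis gene, was named after its value was seen and averaged 4.24 (adjusted p = 0.000333) with incomplete probes included.

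In the list of surface receptors and costimulation, 6 of 25 genes rose and 1 fell (7 and 1 adjusted over the list alone), with a mean of 0.34 and a median of 0.09 (camera, adjusted p = 0.000132, and adjusted p = 0.136 with an estimated correlation). Fisher's exact test of called members did not pass (adjusted p = 0.06). After Cd83, the largest rises were those of the costimulatory receptor gene Cd40, by 2.19 ± 0.04, and the death receptor gene Fas, by 1.16 ± 0.15. Ptafr, the receptor gene for platelet-activating factor, rose by 0.36 ± 0.15, with a mean of 0.10 that did not pass on the arrays with treated RNA in Cy3. Csf3r, the receptor gene for the product of Csf3, fell by 0.17 ± 0.01, was named after its value was seen, and did not pass with set 1, 2 or 3 left out (-0.17, -0.17 and -0.18) or with treated RNA in Cy5 alone (-0.10).

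**Figure D2:**
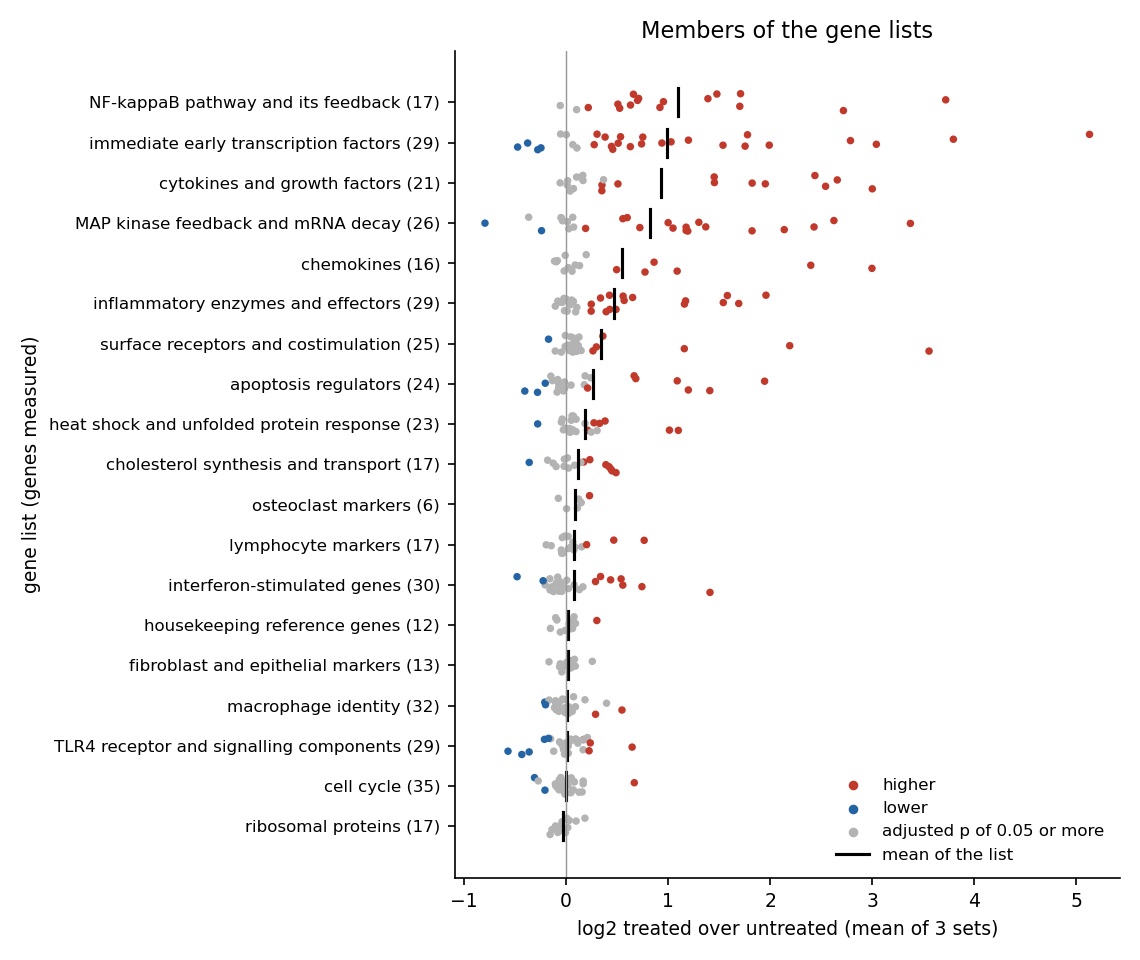
Log2 ratio of treated over untreated RNA (horizontal axis) for each measured member of the 19 gene lists, with 1 point per gene and colour for genes past the test. Bars mark the list means, which run from -0.03 for the ribosomal proteins to 1.09 for the NF-kappaB list.

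TLR4, the LPS receptor, and its signalling components moved both ways, with 4 of 29 genes higher and 5 lower (7 and 6 adjusted over the list alone), and the list as a whole was not shifted (mean 0.01, camera, adjusted p = 0.648), though Fisher's exact test of called members of either direction passed (adjusted p = 0.0233). Tlr4 itself fell by 0.57 ± 0.05 (adjusted p = 0.00053), with probe means of -0.88, -0.66 and -0.17, of which the last did not pass. The kinase adaptor gene Tab1 fell by 0.43 ± 0.06 and Cd180, a relative of Tlr4, fell by 0.36 ± 0.09, the latter without a call when set 1 was left out (-0.33). Tlr2, the receptor gene for bacterial lipopeptides, rose by 0.65 ± 0.02, and the LPS co-receptor gene Cd14 averaged 0.11 ± 0.05 (adjusted p = 0.158), or -0.05 on the arrays with treated RNA in Cy5. Named after their values were seen, the adaptor gene Tirap (-0.21 ± 0.0055), the kinase gene Mapk14 (-0.17 ± 0.0016), the adaptor gene Myd88 (0.17 ± 0.05) and the kinase genes Tbk1 (0.23 ± 0.07) and Mapkapk2 (0.24 ± 0.07) made up the rest of the calls. Without set 1, at -0.21, -0.17, 0.15, 0.18 and 0.28, none of these 5 passed, and Tbk1 alone among them passed without set 2 and without set 3. Tirap was at -0.13 with treated RNA in Cy3 alone, without a call, and Mapk14 had probes at -0.24, which passed, and -0.11, which did not.

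Interferon-stimulated genes had 7 of 30 members that rose and 2 that fell (9 and 5 adjusted over the list alone), with a mean of 0.08 and a test direction upward, a median of -0.05, and no shift (camera, adjusted p = 0.83), though Fisher's exact test of called members passed (adjusted p = 0.0242). Rsad2, an antiviral enzyme gene, rose by 0.74 ± 0.13 and Ifih1, a sensor of viral RNA, by 0.54 ± 0.18. Isg15, a ubiquitin-like modifier, rose by 0.56 ± 0.36 (adjusted p = 0.0389) but did not pass on either dye orientation alone (0.48 and 0.63), after quantile normalization (adjusted p = 0.0517) or with incomplete probes included (adjusted p = 0.117). Without set 1 it passed at 0.35. Ifit3 averaged 1.41 ± 0.23 over probes at 2.90 and -0.08. The 2 that fell, named after their values were seen, were Stat2, a mediator of interferon signalling, which fell by 0.48 ± 0.12, and the GTPase gene Irgm1, which fell by 0.22 ± 0.07 and did not pass without set 1 (-0.21), without set 2 (-0.20) or with treated RNA in Cy3 alone (-0.08).

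Among apoptosis regulators, 7 of 24 genes rose and 3 fell (8 and 3 adjusted over the list alone), with a mean of 0.26, an upward test direction and a median of -0.01. The list did not pass with camera (adjusted p = 0.131), but passed without set 2 (adjusted p = 0.035), with fry (adjusted p = 0.0101) and with Fisher's exact test of called members of either direction (adjusted p = 0.00162). Cflar, an inhibitor of caspase activation, rose by 1.95 ± 0.34, the death promoter gene Bcl2l11 by 1.41 ± 0.06, Mdm2, which restrains p53, by 1.20 ± 0.15 and the survival gene Mcl1 by 1.09 ± 0.05. Named after their values were seen, Pmaip1 fell by 0.40 ± 0.07 and Bid fell by 0.28 ± 0.10, both death promoters, and the survival gene Bcl2 fell by 0.20 ± 0.07. Bid did not pass without set 2 (-0.24) or set 3 (-0.26), and Bcl2 did not with set 1, 2 or 3 left out (-0.22, -0.23 and -0.16). The probes of Bcl2 were at -0.28, which passed, and -0.13, which did not.

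Heat shock and unfolded protein response genes shifted upward, with 6 of 23 that rose and 1 that fell (8 and 1 adjusted over the list alone) and a mean of 0.18 (camera, adjusted p = 0.000378). With an estimated correlation the adjusted p was 0.251, and the list did not pass on the arrays with treated RNA in Cy5 alone (adjusted p = 0.194). Herpud1, which acts in the degradation of misfolded proteins, rose by 1.10 ± 0.06 (its other probe averaged 0.52 over 5 arrays), the stress transcription factor gene Ddit3 by 1.01 ± 0.06, the co-chaperone gene Dnajb1 by 0.38 ± 0.06 and the chaperone gene Hspa5 by 0.33 ± 0.02. Dnajb1 did not pass with treated RNA in Cy3 alone (0.21), nor did Hspa5 in Cy5 alone (0.18). Xbp1, a transcription factor of the same response that was named after its value was seen, fell by 0.28 ± 0.03 and did not pass without set 1 (-0.28) or with treated RNA in Cy3 alone (-0.17).

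Genes of cholesterol synthesis and transport also shifted upward, with 7 of 17 that rose and 1 that fell (8 and 3 adjusted over the list alone) and a mean of 0.12 (camera, adjusted p = 0.0258, and adjusted p = 0.251 with an estimated correlation). Neither orientation alone gave the call, with an adjusted p of 0.0721 for treated RNA in Cy5 and 0.0691 in Cy3. The sterol synthesis genes Cyp51 (0.49 ± 0.07), Msmo1 (0.45 ± 0.06) and Idi1 (0.42 ± 0.05) rose, as did Hsd17b7 (0.44 ± 0.24), which did not pass without set 3 (0.47). Abcg1, a cholesterol exporter gene that was named after its value was seen, fell by 0.36 ± 0.11 and did not pass with treated RNA in Cy5 alone (-0.25).

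Several lists showed no shift. Of all genes tested, 13.2% changed, and a share of calls near this does not set a list apart. For macrophage identity, 2 of 32 genes rose and 2 fell (2 and 2 adjusted over the list alone), with a mean of 0.01, a median of -0.02 and a downward test direction (camera, adjusted p = 0.765). Adgre1, which encodes a surface glycoprotein of mature macrophages, rose by 0.55 ± 0.11 and the protease gene Ctsb rose by 0.29 ± 0.02, the latter not without set 1 (0.28). Fcgr3, an antibody receptor gene, fell by 0.21 ± 0.10 (adjusted p = 0.0462), and Trem2, a lipid receptor gene named after its value was seen, fell by 0.20 ± 0.03. Without set 1, Fcgr3 (-0.21) and Trem2 (-0.19) did not pass, nor did they without set 3 (-0.16 and -0.21), and Trem2 did not without set 2 (-0.20). Fcgr3 also did not pass after quantile normalization (adjusted p = 0.0553), with the probes at or above the median absolute ratio (adjusted p = 0.0545), with incomplete probes included (adjusted p = 0.115) or with zeros kept as ratios (adjusted p = 0.083). Apoe, which encodes a lipid carrier, averaged 0.40 ± 0.31 (adjusted p = 0.0682) and passed without set 3 (0.55).

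In the cell cycle list, 1 of 35 genes rose and 2 fell (4 and 2 adjusted over the list alone), with a mean of -0.0036 (camera, adjusted p = 0.83). Cdkn1a, the gene of the p21 cell cycle inhibitor, rose by 0.67 ± 0.09. The phosphatase gene Cdc25b fell by 0.31 ± 0.09, with probes at -0.45 and -0.17 of which the first passed, and Ccnd1, which encodes cyclin D1, fell by 0.21 ± 0.04. Without set 1 neither Cdc25b (-0.34) nor Ccnd1 (-0.23) passed, and Ccnd1 did not pass without set 2 (-0.19) or set 3 (-0.20) either. With incomplete probes included, Ccnd1 averaged -0.10 (adjusted p = 0.342), and its other probe averaged 0.11 over 4 arrays. With zeros kept as ratios Ccnd1 averaged -0.07. Cdkn1b, another inhibitor of the cycle, averaged -0.27 ± 0.41 (adjusted p = 0.275) and passed without set 2 (-0.51).

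None of the 17 ribosomal protein genes passed, with 0 also adjusted over the list alone, a mean of -0.03 (camera, adjusted p = 0.29) and the largest values at 0.18 ± 0.10 for Rps20 and -0.16 ± 0.04 for Rpl22. Rps20 passed without the replicate block (adjusted p = 0.0306), with a random block (adjusted p = 0.0355) and with treated RNA in Cy5 alone (adjusted p = 0.0495). Among 12 housekeeping reference genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a mean of 0.02 (camera, adjusted p = 0.729). That gene was the transferrin receptor gene Tfrc at 0.30 ± 0.07, which did not pass without set 1 (0.33), with incomplete probes included (0.19) or with zeros kept as ratios (0.12), as its other probe averaged -0.10 over 4 arrays. Actb averaged -0.06 ± 0.07 (adjusted p = 0.477), or 0.04 on the arrays with treated RNA in Cy5. Gapdh averaged -0.01 ± 0.04 (adjusted p = 0.916) over 9 probes from -0.03 to 0.02, and 0.01 on the arrays with treated RNA in Cy3. Ppia, a prolyl isomerase gene, averaged -0.15 ± 0.05 (adjusted p = 0.0688), from -0.83 with treated RNA in Cy5 and 0.52 in Cy3.

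Markers of other cell types were measured as well. Lymphocyte markers had 3 of 17 genes that rose and 0 that fell (3 and 0 adjusted over the list alone), with a mean of 0.08 (camera, adjusted p = 0.189). These were Cd22, a B cell lectin gene, at 0.77 ± 0.12, the T cell co-receptor gene Cd4 at 0.47 ± 0.21 and the B cell receptor component gene Cd79a at 0.20 ± 0.06. With incomplete probes included, Cd22 averaged 0.48 and did not pass (adjusted p = 0.136), and its other probe averaged -0.14 over 4 arrays. In the same fit Cd4 averaged 0.35 and did not pass (adjusted p = 0.207), with other probes at 0.03 and -0.09, nor did it with treated RNA in Cy3 alone (0.30). With zeros kept as ratios Cd22 passed at 0.34 and Cd4 averaged 0.14 without passing. Without set 1, Cd4 (0.52) and Cd79a (0.24) did not pass, and Cd79a did not without set 2 (0.20), without set 3 (0.17) or with a random block (adjusted p = 0.061). Of 13 fibroblast and epithelial markers 0 passed, also adjusted over the list alone, and the mean was 0.02 (camera, adjusted p = 0.648), with Cldn4, a tight junction gene, at 0.26 ± 0.15 (adjusted p = 0.0512). Cldn4 passed without the replicate block (adjusted p = 0.0218), with a random block (adjusted p = 0.0247), with treated RNA in Cy5 alone (adjusted p = 0.0465) and after quantile normalization (adjusted p = 0.047). Osteoclast markers, tested because macrophages can form osteoclasts, had 1 of 6 genes that rose and 0 that fell (2 and 0 adjusted over the list alone), with a mean of 0.09 (camera, adjusted p = 0.131, and 0.0327 without set 1). It was the cell fusion gene Ocstamp, at 0.23 ± 0.09, which did not pass without set 1 (0.21) or set 3 (0.20).

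Altogether camera called 9 of the 19 lists, all upward, while with an estimated correlation it called 0, with 6 at an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance one way, called 10, and Fisher's exact test of called members called 11. On simulated data, camera with an estimated correlation did not call a list of 17 genes raised by 0.25 (adjusted p = 0.158), which the preset correlation of 0.01 called (adjusted p = 1.27e-22). The simulated noise was independent between genes. It therefore cannot tell whether correlation between genes produced the 9 calls.

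The 2 dye orientations served as a check of each ratio. Across probes, which are not independent replicates, the turned log2 ratios of 2 arrays of one orientation correlated with a median Pearson r of 0.741, against 0.377 for arrays that share a set number and 0.397 for pairs that share neither. Among the probes that changed, the medians were 0.959, 0.943 and 0.907. These probes were called from the same 6 arrays, so higher correlations were largely built in by that choice and are no check. Only 6 probes followed the dye at an adjusted p under 0.05, all with lower Cy5 signal and none among the changed probes, while 3182 had an unadjusted p under 0.05. The largest dye difference was that of Sdf2l1, an endoplasmic reticulum protein gene, at -2.81 (Cy5 over Cy3, limma, adjusted p = 0.0315). Of the genes named so far that changed, Fos, Nr4a2, Klf2, Klf4, Dusp14, Csf3r, Ptafr, Tirap, Mapk14, Myd88, Tbk1, Mapkapk2, Isg15, Irgm1, Bid, Bcl2, Dnajb1, Hspa5, Xbp1, Hsd17b7, Abcg1, Fcgr3, Trem2, Cdc25b, Ccnd1, Tfrc, Cd4, Cd79a and Ocstamp did not pass on at least 1 dye orientation alone. With incomplete probes included, Csf3, Ccl5, Isg15, Ptafr, Fcgr3, Ccnd1, Hsd17b7, Tfrc, Cd22, Cd4, Cd79a, Ocstamp, Nr4a2, Klf2, Klf4, Dusp14, Myd88, Tbk1, Mapkapk2, Tirap, Mapk14, Irgm1, Csf3r, Trem2, Bid and Bcl2 did not pass. With zeros kept as ratios, Isg15, Fcgr3, Ccnd1, Hsd17b7, Tfrc, Cd4, Cd79a, Ocstamp, Nr4a2, Myd88, Tbk1, Mapk14, Irgm1, Csf3r and Bcl2 did not pass. After quantile normalization Isg15, Fcgr3 and Myd88 did not pass, and with the probes at or above the median absolute ratio Fcgr3, Myd88 and Csf3r did not. Treating the 6 arrays as separate samples gave 427 probes that followed the dye, and leaving out set 1, 2 or 3 gave 0, 0 and 35.

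**Figure D3:**
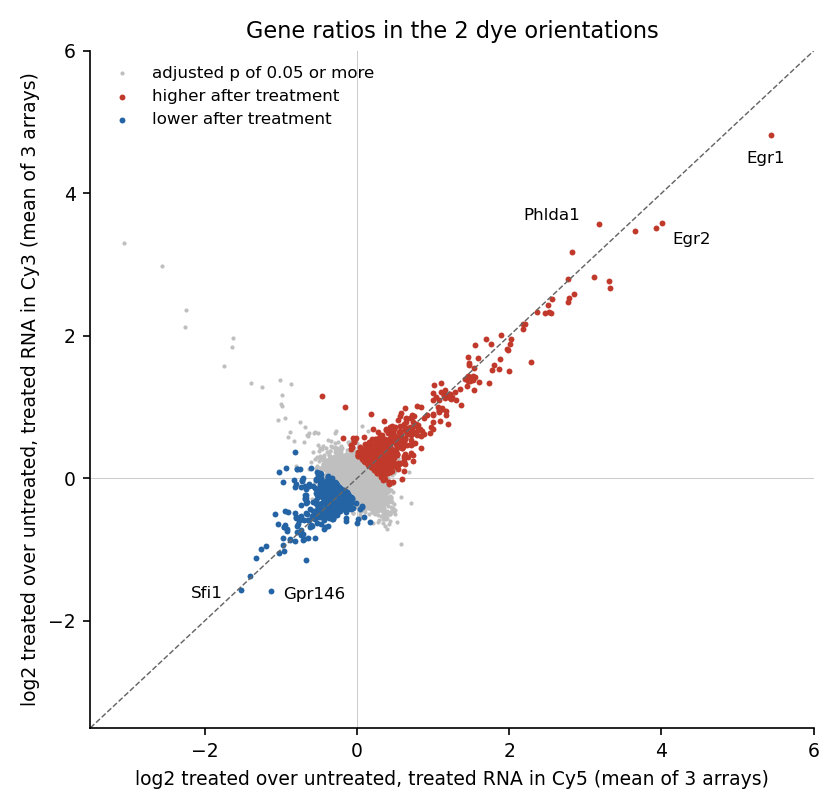
Mean log2 ratio of treated over untreated RNA on the 3 arrays with treated RNA in Cy5 (horizontal axis) and on the 3 with treated RNA in Cy3 (vertical axis), with 1 point per gene and colour for the 580 genes that rose and the 517 that fell. Most genes that changed had one sign on both axes, while 16 had the opposite sign to their mean with treated RNA in Cy5 and 25 with treated RNA in Cy3.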

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

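The tests of probe position and of zeros were chosen only after the results were seen, as were the test of the Zfp genes by dye orientation, their counts after a common shift and their comparison with other genes.

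A total of 6 probes gave a ratio of treated over untreated RNA that differed between the 2 dye orientations. Besides Sdf2l1 at -2.81 (Cy5 over Cy3), they were those of Kl at -2.66, Ctsm at -2.30, Cst7 at -1.97 and Tex47 at -0.63, and 1 probe without a symbol at -1.82 (limma, adjusted p from 0.0199 to 0.0423, n = 3 sets, lower in Cy5 on 6 of 6 arrays). The dye term correlated between neighbouring probe numbers at r = 0.193, above the highest of 1000 shuffles (0.0337) and the 0.0151 of the treatment term, so a part of the dye effect may follow the position of the probe. Across called genes, the dye term and the treatment effect correlated at r = 0.213 (bootstrap SE 0.0332), between the bounds of 0.1 and 0.3 set beforehand, so whether the dye term follows the size of the treatment effect was not settled. No biological explanation was tested.

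Probes listed at 0 limited which genes could be tested. Of 46 ribosomal protein probes, 63.0% were at 0 on at least 1 array, against 27.3% of the other named probes (Fisher's exact test, two-sided, p = 4.68e-07), which is consistent with bright spots beyond the range of the scanner. Of 65 probes for lymphocyte, fibroblast and epithelial markers, 46.2% were at 0 on at least 1 array, against 16% of 50 macrophage identity probes (Fisher's exact test, two-sided, p = 0.000682), which is consistent with dim spots without signal. Both may contribute, no intensities were used here to separate them, and no biological explanation was tested.

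Genes with numbered Zfp symbols, most of them for zinc finger proteins, were lower after treatment more often than other genes, at 34.6% (27 of 78) against 5.94% (Fisher's exact test, two-sided, p = 4.48e-14), and 9 rose. With treated RNA in Cy5 and Cy3, Zfp958 was at -1.08 and -0.50, Zfp53 at -0.90 and -0.47 and Zfp40 at -0.94 and -0.46, the last without a call in Cy3 alone. With 1 orientation alone the share that fell was at least 24.4% (2.99% of the others, Fisher's exact test, two-sided, p = 2.48e-12), which argues against dye bias as the whole cause, although the first criterion, the family's median in each orientation, was -0.12 (bootstrap SE 0.0478) in Cy5 and -0.04 (bootstrap SE 0.0437) in Cy3 and did not decide. Setting array medians to 0, the first test of centring, moved the median of all probes only from -0.0078 to -0.0060. That setting left the family's median at -0.10 and decided nothing. Every gene was then shifted by 0.10, which puts the family's median at 0. After this shift, 26.9% of the family and 3.32% of the others were lower (Fisher's exact test, two-sided, p = 1.48e-13). The shares that were higher were 26.9% and 22.3% (Fisher's exact test, two-sided, p = 0.339). Within the family, 21 genes were lower and 21 were higher. The shift moved all genes alike and put the median of the others at 0.092, which by itself reduces their share of lower genes. The comparison with the others therefore cannot tell whether centring contributed to the lower ratios, and centring stays open. A fall of these transcripts under treatment may account for the pattern, and hybridisation shared among family members was not tested, while list tests differed (limma camera, unadjusted p = 0.000613, and p = 0.0941 with an estimated correlation).

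Splits of the 6 arrays into 2 groups of 3 number 10, too few for a share under 0.05. With the arrays as separate samples, 1 of the 10, the real split, gave the most calls, with 1439 genes against 0 in any other, and 1859 probes against 0. Every other split mixes both orientations in each group, so differences by treatment add to its residual spread and lower its calls. The 0 calls there therefore do not measure how many calls would arise without a treatment effect.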

How the results depend on the processing

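Keeping zeros as ratios, and the dye fit to 6 separate arrays, were alternatives chosen only after the data were seen. As a check of pairing, deviations from the mean of each orientation were correlated across genes between orientations, and set numbers did not pair the arrays: sets 1, 2 and 3 had r = -0.0077, -0.281 and -0.0943 with their own number, against ranges of -0.196 to 0.195, 0.108 to 0.213 and -0.116 to 0.172 with other numbers. Without the replicate block, 1439 genes changed (758 up, 681 down, 1058 of them shared with the 1097) and 1859 probes did, and with a random block (correlation -0.0825) 1340 genes did.

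Leaving out each set gave 621 to 1245 probes, 499 to 832 genes changed, 296 to 471 higher and 203 to 387 lower, 9 to 10 lists, and 0 to 35 dye probes, with the lowest count of changed genes, 499, without set 1 against 831 and 832 without sets 2 and 3, and the cause was not tested. Treated RNA in Cy3 alone gave 837 probes and 649 genes (383 up, 266 down), and the cause was not tested. No filter on missing ratios gave 854 probes and 655 genes (367 up, 288 down), and the cause was not tested. By construction, an adjusted p under 0.01 gave fewer, 715 probes and 538 genes (304 up, 234 down). Camera with an estimated correlation called 0 lists. The dye fit to 6 separate arrays called 427 probes. The median correlation within a set on called probes alone was 0.943, a value favoured by calling those probes from the same arrays. Counts of changed genes stayed within 1.5 times of 1097 under the other alternatives, from 805 with zeros kept to 1439. Some of these could hardly move the count. Leaving out probes with a dye effect removed no called probe, and setting array medians to 0 moved the median of all probes only from -0.0078 to -0.0060. Keeping probes of larger absolute ratio on the same arrays favours called genes.

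The reversed results among genes named by the rule, Tnip2 and the lists had no call to begin with, and the cause was not tested. Among all 1097 changed genes, 16 had the opposite sign with treated RNA in Cy5 alone, of which Il12a was also called (0.35 against -0.46), 25 with treated RNA in Cy3 alone, 2 without the filter on missing ratios (Rgl1 and Slc7a1) and 3 with zeros kept (these and Lifr), and 0 under the other alternatives compared gene by gene. With each set left out, Gapdh ran from -0.027 to 0.010 and Col6a1 from -0.31 to 0.090, both positive without set 2. The camera adjusted p ran from 0.458 to 0.951 for interferon-stimulated genes, reversed without set 2, from 0.562 to 0.781 for macrophage identity, reversed without set 2 (0.702), and from 0.519 to 0.823 for cell cycle, reversed without set 3 (0.749). With Cy5 alone they were Il6 (-0.015), Cd14 (-0.047), Actb (0.040), Tnip2 (0.073), cell cycle (0.989) and housekeeping genes (0.997). With Cy3 alone they were Gapdh (0.0097), Ppia (0.52), Ms4a1 (0.087), Tagln (-0.0096), Krt19 (-0.066), macrophage identity (0.983), ribosomal proteins (0.509) and fibroblast and epithelial markers (0.635). Keeping probes at or above the median absolute ratio reversed macrophage identity (0.989) and cell cycle (0.992), and fry reversed cell cycle (0.932). Fisher's exact test has no direction. Macrophage identity counted as reversed there only because its mean was above 0 while camera's direction was downward.

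Of the other values for named genes, 1279 kept direction and side of the threshold, 57 lost the call and 12 gained it, and for lists these numbers were 273, 13 and 6. For 49 of the genes named after their values were seen, 634 values were kept, 99 lost the call and 1 reversed. Il12a, H2-Q1 and H2-Q4, which changed sign with 1 orientation alone, were not among these genes. A random block and robust eBayes were not run for the list tests.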

Other observations

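The genes and gene families here were chosen after their values were seen, and no explanation of them was tested.

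Outside the lists, Sertad1, a transcriptional co-regulator, rose by 2.47 ± 0.11 (SD, n = 3 sets), or 5.54-fold, and by 1.19 with zeros kept as ratios, and Gpr84, a receptor gene for medium-chain fatty acids, rose by 2.35 ± 0.09. Pde4b, a phosphodiesterase gene that degrades cyclic AMP, rose by 2.17 ± 0.04, and the leukocyte immunoglobulin-like receptor genes Lilrb4a and Lilr4b rose by 1.89 ± 0.11 and 1.89 ± 0.15. Ppp1r15a, which restores translation after stress, rose by 1.65 ± 0.11, Slfn2 by 1.63 ± 0.03 and the ubiquitin ligase gene Peli1 by 1.49 ± 0.08. Within the cytokine list, the anti-inflammatory gene Il10 rose by 1.82 ± 0.06. Falls included Tsc22d3, a glucocorticoid-induced regulator, which fell by 0.91 ± 0.16, Txnip, an inhibitor of thioredoxin, which fell by 0.77 ± 0.10, and the nuclear receptor gene Nr0b2, which fell by 0.84 ± 0.05. The receptor genes Ptgir, for prostacyclin, and Cnr2, for cannabinoids, fell by 0.82 ± 0.01 and 0.76 ± 0.11, and the kinase gene Map3k14, of noncanonical NF-kappaB signalling, fell by 0.74 ± 0.10. The transcription factor genes Hivep2 and Zbtb1 fell by 0.84 ± 0.16 and 0.82 ± 0.14. Each of these genes had the same sign on 6 of 6 arrays and passed with any 1 set left out.

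Among 30 families of at least 20 genes that share a symbol stem, 1 passed for rises and 2 for falls (Fisher's exact test, two-sided, adjusted over both directions). The H2 genes of the major histocompatibility complex had 10 of 26 members that rose and 0 that fell (adjusted p = 0.000142), counts that were 9 and 0 after quantile normalization. The largest rises were those of H2-K2 by 1.05 ± 0.37, H2-M2 by 0.45 ± 0.06 and H2-Q7 by 0.42 ± 0.03. H2-K1, a classical class I gene, rose by 0.20 ± 0.05 and did not pass without set 1 (0.21), set 2 (0.17) or set 3 (0.21). On either orientation alone it did not pass (0.29 with treated RNA in Cy5 and 0.10 in Cy3). Nor did it with incomplete probes included (limma, adjusted p = 0.083) or with zeros kept as ratios (adjusted p = 0.0558). With treated RNA in Cy3 alone, H2-Q1 (0.19 over all arrays) and H2-Q4 (0.17) were at -0.05 and -0.08. Hybridisation shared among H2 genes was not tested. The Tmem genes, which share only a predicted membrane span, had 13 of 73 members that fell and 4 that rose (adjusted p = 0.00963), 12 of them lower with array medians at 0. The other family was that of the Zfp genes (adjusted p = 2.69e-12), with 26 lower after quantile normalization.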
